A study of Homo sapiens with 18 samples.

How the data were processed

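RNA sequencing of 16 libraries from 3 established human head and neck squamous carcinoma cell lines was analysed. A253 gave 3 control and 3 EHF overexpression libraries, and SCC25 gave 2 control and 2 EHF overexpression libraries. CAL27 gave 2 control libraries and 2 libraries from each of 2 EHF knockdowns. A CAL27 EHF ChIP library and its input DNA, 1 of each, were not analysed here. Per the labels, RNA was extracted with Trizol, enriched for mRNA and prepared with a TruSeq RNA kit. The labels state that overexpressing cells grew in medium with doxycycline and control cells in regular medium, so doxycycline and EHF overexpression cannot be told apart in these libraries. The labels name TopHat2 2.1.1, featureCounts 1.5.3, Bowtie 1.1.1 and DESeq2 1.12.4 and the hg19 genome build. The labels do not say whether replicates of a group are separate cultures, so every p-value measures only the spread between these samples.

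The deposited count tables hold raw counts per gene symbol, made by the authors, 1 table per cell line with 23710 genes each. The deposited TPM tables hold TPM for the same genes. In the deposited SCC25 table the unit is a score rather than TPM: its values were counts divided by gene length 2 times, with a slope of 2 between its implied log2 lengths and those of A253 over 18479 genes, and its header was shifted by 1 cell. In the alternative on TPM these SCC25 values were used as they are, so that the pseudocount weighs more on long genes there than in the other lines. In the count table of CAL27, the names of 696 genes had been altered, and 692 of these were names that hold R1 or R2. Names were taken by position from the CAL27 TPM table, after checking that the length implied by counts and TPM equalled that in A253 within 0.01 on the log2 scale for 18450 of 18450 genes with both, including 398 of 398 altered names. Another 28 names had turned into dates and 2 names occurred more than once.

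The CAL27 count and TPM tables give the names of the knockdowns, sh 64 and sh 65, the other way round. The pattern of zeros in each sh 64 count library matched a TPM column named sh 65 for 100 percent of genes, and the reverse. Replicate numbers differed too for sh 64: its count replicates 1 and 2 matched TPM replicates 2 and 1. Replicate numbers here are those of the count table. Names from the count table are used here, and the labels do not tie either name to knockdown 1 or knockdown 2. The mean of both knockdowns against control does not depend on this naming. Alternatives on TPM were not run for the separate knockdowns. The mitochondrial genome transcripts of 1 planned list are missing from the tables, and genes are given by symbol without coordinates because the annotation available was for another genome build.

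Library totals were 11090976 to 17823293 counts in A253, 10728569 to 15965279 in SCC25 and 7068155 to 19962159 in CAL27. Counts were analysed with edgeR 4.0.16 in R 4.3.3: genes were filtered with filterByExpr, libraries were scaled by TMM, and a robust quasi-likelihood model was fitted per cell line, with all CAL27 groups in 1 fit. P-values are two-sided and were adjusted by the method of Benjamini and Hochberg over the genes tested, with a threshold of 0.05. Expression levels are CPM (counts relative to the TMM-scaled library total) with the standard deviation between libraries. The effect in SCC25 was compared with that in A253 by an interaction term in a joint fit of both lines. The effect called common to both lines is an average over them, from an additive model with the cell line as covariate. Where the libraries of a control group held 1 to 3 counts of a gene in all, the ratio of library-scaled counts is given with an exact interval at a confidence level of 0.95. Such intervals cover counting error only.

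There were 28 gene lists, on epidermal differentiation, basal keratinocytes, epithelial adhesion, mesenchyme and matrix, NRF2 targets, other redox enzymes, glycolysis, oxidative phosphorylation, hypoxia, the ATF4 response, endoplasmic reticulum chaperones, cholesterol synthesis, S phase, mitosis, type I interferon, NF-kB, host defence, ERBB signalling, ERK feedback, immediate early genes, ETS factors, mitochondrial transcripts, replication-dependent histones, and markers of fibroblasts, leukocytes, endothelium, salivary gland and myoepithelium. Lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, and the adjusted p of a list is over the lists of its comparison. Camera with an estimated correlation and fry were run beside it. Members past the threshold are also counted adjusted over the list alone. The lists, comparisons, tests, alternatives and the rule for named genes were chosen before the data were examined.

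Genes were named by this rule: EHF, then the 5 largest rises and 5 largest falls past the threshold with an average log2 CPM of at least 2 and no overlap between the groups. From each list past the camera threshold, and in any case from the lists on epidermal differentiation, NRF2, redox, glycolysis and ETS factors, up to 3 called members with the largest change were added. The 10 genes with the largest minimum change among those moved oppositely by overexpression and knockdown were named, as were the 3 highest and 3 lowest differences between lines and between knockdowns. EHF was left out of these rankings. Genes named outside the rule were chosen after their values were seen, and this is stated beside them. Reads of the near-identical members of the SERPINB, AKR1C, SPRR1, IFITM, HLA and histone families cannot be assigned to 1 gene with certainty.

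Alternatives were RLE size factors, DESeq2 1.42.0, no filter on low counts, a CPM minimum of 1 in 2 libraries, the replicate number as a block, limma on log2 TPM with pseudocounts of 1 and 0.1 and without a filter, a 2-fold minimum, and leaving out each library in turn. Replicate numbers paired the libraries weakly at most. After group means were removed, correlations between libraries of the same number were -0.19, 0.01 and 0.18 in A253 and -0.03 in SCC25. In CAL27 they were -0.01, 0.15 and 0.09. The block was therefore kept as an alternative. In CAL27 it raised the count for the mean knockdown from 2560 to 3317, so some spread may follow the replicate numbers there. The overlap of the knockdowns, which share controls, was set beside 40 simulations of unchanged groups against shared controls. For genes called in all 3 lines, the expected number keeps the calls shared by both overexpression comparisons and takes the knockdown calls as independent of them, a choice made after the values were seen. The procedure was tested on simulated data with the size and spread of each comparison. There edgeR recovered 82.1 percent of genes changed 2-fold in A253, 89.6 percent in SCC25 and 85.1 percent in the mean of the knockdowns, with 10.1, 5.91 and 15.1 percent of its calls false. Tables were prepared and drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.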

Results

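Gene expression was measured by RNA sequencing after the level of EHF, an epithelial transcription factor of the ETS family, was changed in 3 head and neck squamous carcinoma cell lines. EHF was overexpressed in A253 (3 control and 3 overexpression libraries) and SCC25 (2 and 2), and knocked down in CAL27 (2 control libraries, 2 with sh 64 and 2 with sh 65, named as in the count table). Library totals ran from 7068155 to 19962159 counts. The comparisons ask which genes follow EHF when it is raised or lowered, and whether lines and knockdowns respond alike. Overexpressing cells were the ones grown with doxycycline, so each overexpression effect includes any effect of the drug.

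EHF was lowest in A253 controls, at 86.3 ± 4.42 CPM (SD, n = 3), and rose 8.13-fold to 702 ± 66.5 CPM (SD, n = 3) with overexpression (log2 change 3.02, SE 0.079, adjusted p = 4.63e-13). In SCC25 it rose 1.99-fold, from 440 ± 28.7 to 875 ± 23.2 CPM (SD, n = 2; adjusted p = 9.11e-13). CAL27 controls held the most EHF, 976 ± 20.9 CPM (SD, n = 2). Knockdown left 511 ± 20.5 CPM with sh 64 and 456 ± 18.2 CPM with sh 65 (SD, n = 2 each), log2 changes of -0.94 (adjusted p = 1.68e-07) and -1.10 (adjusted p = 1.8e-08). The mean log2 change of the knockdowns was -1.02 (SE 0.059, adjusted p = 1.35e-08). Knockdown was therefore partial. EHF did not differ past the threshold between sh 65 and sh 64 (log2 difference -0.16, adjusted p = 0.23).

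**Figure D1:**
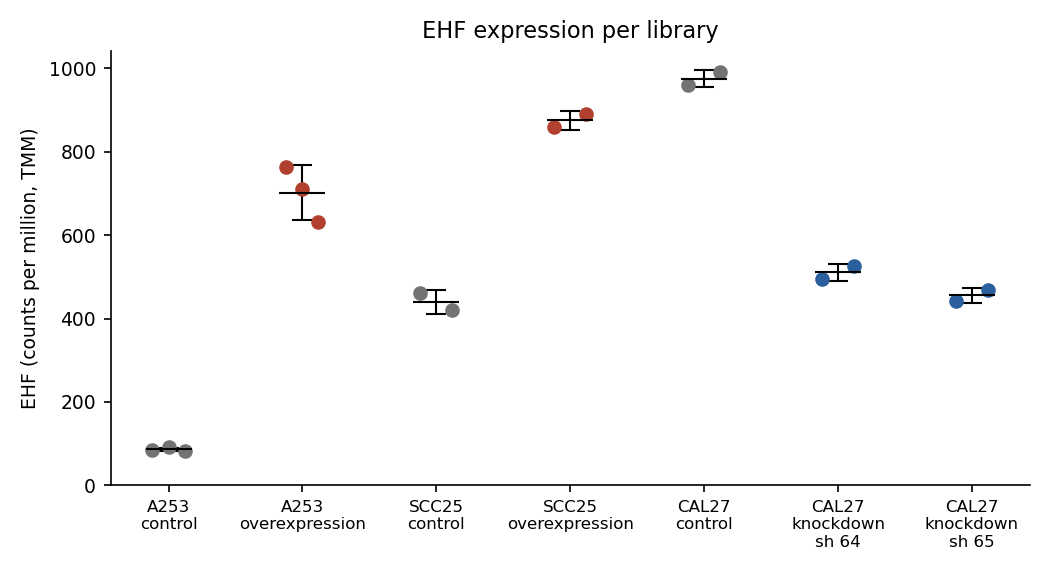
EHF expression in TMM-scaled CPM (vertical axis) in each of the 16 RNA libraries, by group (horizontal axis); points are libraries, and the line and bars are the group mean and SD. The mean rose from 86.3 to 702 in A253 and from 440 to 875 in SCC25, and fell from 976 to 511 and 456 in CAL27.

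Several genes that A253 controls barely expressed rose with overexpression. SPP1, which encodes the secreted matrix protein osteopontin, went from 3 counts in all control libraries to 843 counts with overexpression, a ratio of 284 (counting interval 96.9 to 1380). DHRS9, a retinol dehydrogenase, rose 26-fold to 22.2 ± 1.43 CPM, and FRMD3 rose 15.6-fold to 21.9 ± 2.09 CPM (SD, n = 3). KIAA1199, a protein of hyaluronan breakdown, rose 6.91-fold from 10.5 ± 1.2 to 73.3 ± 7.91 CPM, and S100A9, a subunit of calprotectin, rose 6.67-fold from 8.34 ± 0.807 to 55.4 ± 3.33 CPM. Falls were smaller: the neural adhesion molecule NCAM1 (log2 change -1.25), the placental alkaline phosphatase ALPP (-1.10), the tubulin TUBA1A (-1.10), the aldo-keto reductase AKR1C1 (-1.01) and the pro-apoptotic gene BMF (-0.93) fell. The call of BMF ended on TPM without a filter (adjusted p = 0.0653).

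Of 14503 genes tested in A253, 1156 passed the threshold, 730 higher and 426 lower, and 157 of these changed at least 2-fold (130 higher, 27 lower). The count was 658 without control replicate 1, and 699, 687 and 561 in the alternatives on TPM with a pseudocount of 1, of 0.1, and of 1 with no filter. With the replicate number as a block it was 1073.

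Epithelial host defence genes, which encode antimicrobial and mucosal proteins, rose in A253. Of 24 tested, 11 rose and 3 fell (11 and 4 adjusted over the list alone), with a median log2 change of 0.31. The list passed by camera (adjusted p = 7.92e-05, and adjusted p = 0.255 with an estimated correlation). Other splits of the A253 libraries passed up to 7 lists by camera, against 5 for the real one, so the number of lists does not stand out. LCN2, an antimicrobial protein that binds iron carriers, rose 16.9-fold, from 0.294 ± 0.242 to 5.62 ± 0.73 CPM (SD, n = 3). In the type I interferon list 19 of 43 tested genes rose and 2 fell (20 and 4 adjusted over the list alone, median 0.20, camera adjusted p = 3.18e-05, and adjusted p = 0.255 with an estimated correlation). SAMD9L, an antiviral factor, rose 2.12-fold from 52.4 ± 4.53 to 111 ± 8.67 CPM. NF-kB targets and cytokines gave 8 rises and 1 fall among 25 (11 and 1 adjusted over the list alone, median 0.28, camera adjusted p = 0.000618, and adjusted p = 0.255 with an estimated correlation). These included the apoptosis inhibitor BIRC3 (log2 change 0.99) and the cytokine IL1A (0.83). DESeq2 called 3 rises.

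Epidermal differentiation genes moved the other way in A253. Of 36 tested, 1 rose and 6 fell (3 and 6 adjusted over the list alone, median -0.19, camera adjusted p = 0.00632, and adjusted p = 0.255 with an estimated correlation). The suprabasal keratin KRT1 (log2 change -1.93) and ABCA12, a lipid transporter of the skin barrier (-0.86), fell. ABCA12 did not pass on TPM with a pseudocount of 1 (adjusted p = 0.0659), of 0.1 (adjusted p = 0.0694) or without a filter (adjusted p = 0.0812). Nuclear-encoded genes of oxidative phosphorylation shifted by a small median of 0.10: 3 of 74 rose by edgeR and 2 by DESeq2, 0 passed by edgeR when adjusted over the list alone and 16 had an unadjusted p under 0.05. By camera the list passed (adjusted p = 0.000118, and adjusted p = 0.844 with an estimated correlation). Without control replicate 2 that median was 0.04 (adjusted p = 0.301). Among single genes of glycolysis and redox, PKM, a pyruvate kinase, rose 1.83-fold from 1890 ± 96.5 to 3450 ± 108 CPM (SD, n = 3). TXNIP, which binds thioredoxin, rose by 0.87 and XDH, xanthine dehydrogenase, by 0.64. Falls were as many in these lists: DESeq2 called 2 rises and 2 falls of glycolysis genes, and 2 and 2 of other redox enzymes. Of the 43 genes named by the rule in A253, 10 lost their call without control replicate 1, 10 without control replicate 2 and 9 without overexpression replicate 3; none of these is among the A253 genes given so far.

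In SCC25, EHF rose less than in A253 and more genes passed, except on TPM without a filter. Values named TPM for SCC25, here and below, are the score described above. These counts come from unlike designs, with 2 libraries per group in SCC25 and 3 in A253. The spread differed too, with a common coefficient of variation of 0.0587 in SCC25 and 0.08 in A253. MMP13, a collagenase, rose 15.5-fold from 133 ± 12.5 to 2060 ± 181 CPM (SD, n = 2), and B4GALNT2, a glycosyltransferase, rose 14.7-fold from 4.18 ± 0.554 to 62 ± 1.79 CPM. KIAA1199 rose here too, 11.7-fold from 5.43 ± 0.256 to 63.8 ± 0.853 CPM, and LAPTM5, a lysosomal membrane protein, 7.16-fold from 4.64 ± 0.251 to 33.2 ± 0.986 CPM. HLA-G, a non-classical antigen-presenting molecule, had 0.962 ± 1.17 CPM in controls and 18.6 ± 1.75 CPM with overexpression (SD, n = 2; log2 change 4.22, adjusted p = 0.0116). Its controls were unequal: the change was 7.02 without control replicate 1 and 3.38 without control replicate 2. It did not pass with the replicate block (adjusted p = 0.187) or on TPM without a filter (adjusted p = 0.0595). The innate immune receptor TREM1 (log2 change -1.34), the tryptophan-degrading enzyme TDO2 (-1.26), the pseudogene HTATSF1P2 (-1.21), the receptor TNFRSF8 (-1.17) and the hyaluronan-binding protein TNFAIP6 (-1.07) fell.

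In SCC25, 3370 of 14120 genes passed, 1728 higher and 1642 lower, but only 192 changed at least 2-fold (164 higher, 28 lower). DESeq2 called 1540 genes, limma on TPM called 1234, 1604 and, with no filter, 96, and the count was 2228 and 2124 without overexpression replicates 1 and 2. With the replicate block it was 3521. The 2 overexpression libraries differed by a chi-square per degree of freedom of 17.9 and the 2 controls by 3.08. Their log2 CPM correlated at 0.9953 and 0.9971. The balance of rises and falls turned with no filter on low counts (1713 higher, 1949 lower), on TPM with a pseudocount of 1 (575 and 659) or 0.1 (731 and 873), and without control replicate 1 (1800 and 1839). On TPM without a filter 54 of the 70 genes named by the rule lost their call. As these SCC25 values are the score rather than TPM, such losses can come from that unit.

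Defence and interferon genes rose in SCC25. Of 28 host defence genes, 21 rose and 0 fell (22 and 1 adjusted over the list alone, median 0.63, camera adjusted p = 1.26e-14, and adjusted p = 0.245 with an estimated correlation). The membrane mucin MUC4 rose by 3.61 on the log2 scale, PIGR, the transporter of secretory antibodies, by 2.20, and LCN2 3.67-fold from 25.2 ± 0.852 to 92.3 ± 3.65 CPM (SD, n = 2). By limma on the SCC25 score without a filter MUC4 (adjusted p = 0.549) and PIGR (adjusted p = 0.212) did not pass. In that score the pseudocount weighs more on long genes, and the log2 change of MUC4 was only 0.019. DESeq2 called 13 rises of host defence genes. Of 41 interferon genes, 28 rose and 0 fell (31 and 0 adjusted over the list alone, median 0.34, camera adjusted p = 6.41e-17, and adjusted p = 0.25 with an estimated correlation). These included IFITM1, which restricts virus entry (0.97), and SAMD9L (0.91). Immediate early genes, 6 of 20 higher and 0 lower (6 and 0 adjusted over the list alone, median 0.18), passed weakly (camera adjusted p = 0.029, and adjusted p = 0.25 with an estimated correlation), with the stress factor ATF3 higher by 1.16. That list did not pass without control replicate 1 (adjusted p = 0.0822) or overexpression replicate 2 (adjusted p = 0.102), nor on TPM with a pseudocount of 1 (adjusted p = 0.0594), of 0.1 (adjusted p = 0.0998) or without a filter (adjusted p = 0.0764).

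Structural genes of the epithelium and the matrix rose as well in SCC25. Epidermal differentiation genes gave 14 rises and 1 fall among 39 (15 and 1 adjusted over the list alone, median 0.19, camera adjusted p = 1.42e-05, and adjusted p = 0.228 with an estimated correlation). These included the cornified envelope protein IVL (1.42) and the keratin KRT4 (1.17), and DESeq2 called 7 rises. Basal keratinocyte genes gave 12 rises and 2 falls among 25 (14 and 3 adjusted over the list alone, median 0.14, camera adjusted p = 5.09e-05, and adjusted p = 0.228 with an estimated correlation), with the basal keratin KRT15 higher by 0.85 and the stem cell factor SOX2 lower (-0.65). For epithelial adhesion the counts were 17 and 1 of 42 (18 and 1 adjusted over the list alone, median 0.13, camera adjusted p = 4.75e-06, and adjusted p = 0.228 with an estimated correlation). Among them the tight junction protein CLDN4 fell (-0.82). Mesenchymal and matrix genes gave 19 rises and 2 falls of 37 (21 and 4 adjusted over the list alone, median 0.27, camera adjusted p = 2.26e-07, and adjusted p = 0.228 with an estimated correlation). These included MMP13, the contractile gene TAGLN (0.91) and the matrix protein TNC (0.86). Myoepithelial markers moved with them: 3 of 7 rose (3 and 0 adjusted over the list alone, median 0.35, camera adjusted p = 0.0282, and adjusted p = 0.25 with an estimated correlation), with TAGLN shared between both lists and CALD1 higher by 0.37. The marker list did not pass without control replicate 1 (adjusted p = 0.0986) or overexpression replicate 2 (median 0.03, adjusted p = 0.0869). Endoplasmic reticulum chaperones had 8 rises and 1 fall of 21 (8 and 1 adjusted over the list alone, median 0.07, camera adjusted p = 0.029, and adjusted p = 0.25 with an estimated correlation), with DNAJB9 higher by 0.48. Their call ended without control replicate 1 (adjusted p = 0.102), overexpression replicate 1 (adjusted p = 0.112) or 2 (adjusted p = 0.234), and on TPM with a pseudocount of 1 (adjusted p = 0.226), of 0.1 (adjusted p = 0.301) or without a filter (adjusted p = 0.179).

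Genes of cell division and of metabolism fell in SCC25. All 47 tested replication-dependent histone genes fell (47 also adjusted over the list alone, median -0.48, camera adjusted p = 2.67e-40, and adjusted p = 0.25 with an estimated correlation); the linker histone HIST1H1A went from 82.7 ± 3.1 to 47.5 ± 1.14 CPM (SD, n = 2). Of 43 S phase genes 32 fell and 0 rose (34 and 0 adjusted over the list alone, median -0.27, camera adjusted p = 1.53e-15, and adjusted p = 0.245 with an estimated correlation). These included the replicative helicase subunit MCM2 (-0.46). Of 52 mitosis genes 35 fell and 0 rose (42 and 0 adjusted over the list alone, median -0.19, camera adjusted p = 2.68e-15, and adjusted p = 0.245 with an estimated correlation). These included the spindle kinase AURKB (-0.43). Oxidative phosphorylation genes gave 29 falls and 0 rises of 74 (38 and 0 adjusted over the list alone, median -0.14, camera adjusted p = 2.47e-10, and adjusted p = 0.402 with an estimated correlation). These included CYC1, a cytochrome (-0.30). Cholesterol synthesis genes gave 13 falls and 0 rises of 25 (18 and 1 adjusted over the list alone, median -0.23, camera adjusted p = 1.94e-07, and adjusted p = 0.228 with an estimated correlation). These included INSIG1, a sterol sensor (-0.54). Glycolysis genes had 13 falls and 2 rises of 26 (15 and 4 adjusted over the list alone, median -0.20, camera adjusted p = 0.00041, and adjusted p = 0.307 with an estimated correlation). These included the enolase ENO1 (-0.39). In the NRF2 list, genes of the antioxidant response, 18 of 37 fell and 3 rose (22 and 3 adjusted over the list alone, median -0.18, camera adjusted p = 8.22e-07, and adjusted p = 0.25 with an estimated correlation). These included AKR1C1 (-0.83) and the glutathione peroxidase GPX2, which went from 111 ± 0.858 to 63 ± 1.66 CPM. DESeq2 called 45 falls of histone genes, 13 of oxidative phosphorylation genes and 11 of NRF2 targets. Outside these lists the oxidase DUOX2 rose by 1.19, and the ETS factors ETV1 and ETV5 fell (-1.47 and -0.99). By limma on the SCC25 score without a filter these 3 did not pass (adjusted p = 0.194, 0.136 and 0.194). Their lists were divided: DESeq2 called 6 rises and 4 falls of other redox enzymes, and 2 and 3 of ETS factors.

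Knockdown of EHF in CAL27 raised genes of the differentiating squamous epithelium. Against control, as the mean of both knockdowns, KRT19, a simple epithelial keratin, rose 7.39-fold from 0.88 ± 0.317 (SD, n = 2) to 6.07 ± 1.96 CPM (SD, n = 4). SPRR1B, a precursor of the cornified envelope, rose 6.19-fold from 2.51 ± 0.0485 to 15.8 ± 3.24 CPM, its paralog SPRR1A 4.95-fold, and the niacin receptor HCAR2 4.44-fold. The keratin KRT4 rose 6.45-fold on average, mostly with sh 65, from 0.519 ± 0.265 to 1.18 ± 0.0733 CPM with sh 64 and 12.2 ± 2.52 CPM with sh 65 (SD, n = 2 each). Among genes with an average log2 CPM of at least 2, the largest falls were those of the transglutaminase TGM2, from 20.1 ± 1.4 to 4.21 ± 2.09 CPM, the cytokine CSF2, from 12.8 ± 1.79 to 3.08 ± 2.06 CPM, LAPTM5 (-2.03), the antimicrobial ribonuclease RNASE7 (-1.92) and the RNA-binding protein SAMD4A (-1.77).

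Of 13629 genes tested in CAL27, 2560 passed, 1346 higher and 1214 lower, and 293 changed at least 2-fold (234 higher, 59 lower). The count was 937 and 1037 without control replicates 1 and 2, 1461 by DESeq2, and 1628, 1635 and 855 on TPM with a pseudocount of 1, of 0.1 and without a filter. With the replicate block it was 3317. The balance turned on TPM with a pseudocount of 1 (658 higher, 970 lower), of 0.1 (659 and 976) and without a filter (389 and 466). TPM values were not scaled by TMM, and log2 changes in these settings shifted by a median of -0.053, -0.055 and -0.053. That shift goes in the direction of the turned balance. On TPM without a filter 12 of the 54 genes named by the rule lost their call.

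Several programmes rose with knockdown. Of 34 epidermal differentiation genes 23 rose and 0 fell (24 and 0 adjusted over the list alone, median 0.78, camera adjusted p = 2.19e-14, and adjusted p = 0.0906 with an estimated correlation). Epithelial adhesion genes gave 15 rises and 4 falls of 43 (16 and 4 adjusted over the list alone, median 0.16, camera adjusted p = 5.15e-05, and adjusted p = 0.091 with an estimated correlation). These included the desmosomal protein PKP1, which rose from 58.3 ± 2.35 to 141 ± 6.88 CPM, and the claudin CLDN7 (1.07). Interferon genes gave 35 rises and 0 falls of 43 (37 and 0 adjusted over the list alone, median 0.49, camera adjusted p = 7.58e-23, and adjusted p = 0.13 with an estimated correlation); IFI27 rose 2.03-fold from 53.2 ± 6.73 to 110 ± 14.2 CPM. The ATF4 list, the response to amino acid shortage, gave 19 rises and 1 fall of 34 (23 and 1 adjusted over the list alone, median 0.36, camera adjusted p = 9.47e-11, and adjusted p = 0.0906 with an estimated correlation). These included PHGDH of serine synthesis, which rose 2.22-fold from 41.8 ± 3.93 to 93.6 ± 13 CPM. NRF2 targets gave 19 rises and 1 fall of 37 (22 and 1 adjusted over the list alone, median 0.27, camera adjusted p = 1.16e-08, and adjusted p = 0.0906 with an estimated correlation). These included AKR1C3 (1.76) and AKR1C2 (1.59). Oxidative phosphorylation genes gave 24 rises and 0 falls of 74 (31 and 2 adjusted over the list alone, median 0.17, camera adjusted p = 1.12e-08, and adjusted p = 0.505 with an estimated correlation). These included ATP5I (0.43). Replication-dependent histones rose in 7 of 47 cases (5 adjusted over the list alone, median 0.10, camera adjusted p = 0.000102, and adjusted p = 0.505 with an estimated correlation), with HIST1H3E higher by 1.13. The histone median was -0.05 with sh 64 (camera adjusted p = 0.158) and 0.26 with sh 65 (camera adjusted p = 7.14e-16, and adjusted p = 0.188 with an estimated correlation). DESeq2 called 12 rises of oxidative phosphorylation genes and 2 of histone genes.

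Matrix and replication genes fell with knockdown, and NF-kB targets fell with sh 65 but not with sh 64. Of 35 mesenchymal and matrix genes 22 fell and 2 rose (24 and 2 adjusted over the list alone, median -0.40, camera adjusted p = 2.58e-11, and adjusted p = 0.103 with an estimated correlation). The cadherin CDH11 fell by 2.71 on the log2 scale, and MMP13 rose by 2.01, a call that ended without control replicate 1 (adjusted p = 0.108) or 2 (adjusted p = 0.0934). In the mean of both knockdowns NF-kB targets gave 16 falls and 3 rises of 31 (18 and 3 adjusted over the list alone, median -0.36, camera adjusted p = 1.2e-05, and adjusted p = 0.284 with an estimated correlation). These included CSF2 (-2.28) and the cytokine IL32 (-1.03). With sh 64 alone 9 of the list rose and 3 fell (median 0.04), and with sh 65 alone 1 rose and 19 fell (median -0.86). At an estimated correlation 0 lists passed with sh 65 against control, and 0 between sh 65 and sh 64. S phase genes gave 19 falls and 0 rises of 43 (26 and 0 adjusted over the list alone, median -0.20, camera adjusted p = 9.47e-11, and adjusted p = 0.122 with an estimated correlation). These included CDCA7 (-0.57). DESeq2 called 12 falls of S phase genes. Host defence genes were divided, with 7 rises and 7 falls of 25 (9 and 7 adjusted over the list alone, median 0.24, camera adjusted p = 0.0287, and adjusted p = 0.505 with an estimated correlation): the calprotectin subunit S100A8 rose by 1.70 and the protease inhibitor PI3 by 1.54, while RNASE7 fell. Their median was 0.39 with sh 64 (camera adjusted p = 6.24e-05, and adjusted p = 0.285 with an estimated correlation) and 0.12 with sh 65 (camera adjusted p = 0.824). Outside these lists AOX1, aldehyde oxidase, fell (-1.76). SESN3, a sestrin of the stress response, rose by 1.30, the glucose transporter SLC2A1 by 0.52, and the epithelial ETS factor ELF3 by 1.17. At an unadjusted p under 0.05 by edgeR, 2 glycolysis genes rose and 5 fell, and in the ETS list 4 rose and 4 fell.

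**Figure D2:**
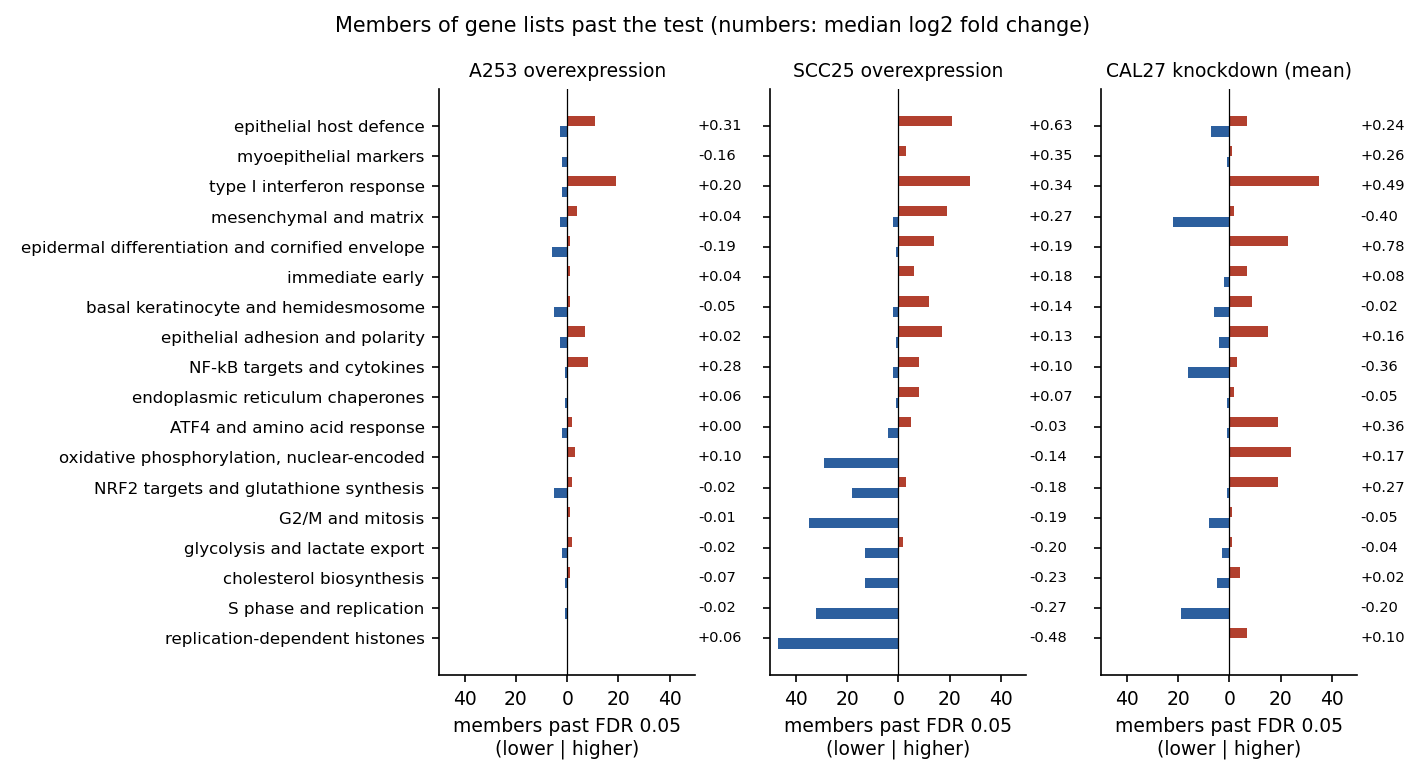
Members of each gene list past FDR 0.05 in A253 overexpression, SCC25 overexpression and CAL27 knockdown (mean of both), against the control of each line; horizontal bars count members higher (red, right) or lower (blue, left), and numbers give the median log2 fold change of the list. Interferon genes were higher in each comparison (19, 28 and 35 members), and histone genes were lower in SCC25 (47 members).

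The knockdowns overlapped more than independent lists would. With sh 64, 2133 genes passed (1194 higher, 939 lower), and with sh 65, 1994 (1038 higher, 956 lower; 582 and 588 by DESeq2). Both raised 576 genes and both lowered 440 (1016 in all), where independent lists would share 90.9 and 65.9, while 26 rose with sh 64 and fell with sh 65 and 1 did the reverse. In 40 simulations of unchanged groups against the same controls the shared counts averaged 0.525 and 0.375, but only 4.75 and 3.75 genes passed there on average, so these say little about lists of this length. Across genes, which are not independent replicates, the log2 changes correlated with Pearson r = 0.682 and Spearman rho = 0.621, where shared controls alone gave a mean r of 0.437 (0.467 at most). Their covariance was 0.116, against a mean of 0.0194 in the simulations. Part of the overlap can come from the shared controls. Interferon genes rose with each (27 of 43 with sh 64 and 35 of 43 with sh 65, camera adjusted p = 1.65e-16 and 6.07e-25, and adjusted p = 0.171 and 0.116 with an estimated correlation). Epidermal differentiation genes did too (16 and 18 of 34, camera adjusted p = 4.05e-10 and 1.83e-14, and adjusted p = 0.124 and 0.0801 with an estimated correlation). DESeq2 gave 1191 and 1170 genes for sh 64 and sh 65, and 562 shared. Without control replicate 1 the counts were 866, 879 and 390, without control replicate 2 they were 940, 937 and 446, and without sh 64 replicate 1 the sh 64 and shared counts were 899 and 530. A 2-fold minimum left 308, 341 and 146. With the replicate block they were 2968, 2715 and 1473.

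The knockdowns differed in inflammatory genes. Between sh 65 and sh 64, 728 of 13629 genes passed, 301 higher and 427 lower with sh 65 (524 and 524 without sh 65 replicate 2). IL1A was 196 ± 15.7 CPM with sh 64 and 31.7 ± 1.8 CPM with sh 65 (SD, n = 2 each), and SERPINB2, an inhibitor of plasminogen activators, and CYP1A1, a target of the aryl hydrocarbon receptor, were lower with sh 65 by log2 differences of -2.74 and -2.53. KRT4 (3.34), LYPD1 (1.97) and ALPP (1.85) were higher with sh 65. Of 31 NF-kB targets 18 were lower and 0 higher (24 and 0 adjusted over the list alone, median -0.76, camera adjusted p = 1.59e-29, and adjusted p = 0.147 with an estimated correlation). Against control, the median of this list was 0.04 with sh 64 (camera adjusted p = 0.0864) and -0.86 with sh 65 (camera adjusted p = 1.93e-16, and adjusted p = 0.0838 with an estimated correlation). Cholesterol synthesis genes were lower with sh 65 in 18 of 25 cases (20 adjusted over the list alone, median -0.51, camera adjusted p = 8.1e-22, and adjusted p = 0.147 with an estimated correlation), and histone genes were higher in 26 of 47 (44 adjusted over the list alone, median 0.30, camera adjusted p = 1.11e-28, and adjusted p = 0.147 with an estimated correlation). The gene count was 263 and 419 without sh 64 replicates 1 and 2, 441 by DESeq2, 120 with a 2-fold minimum and 1260 with the replicate block.

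**Figure D3:**
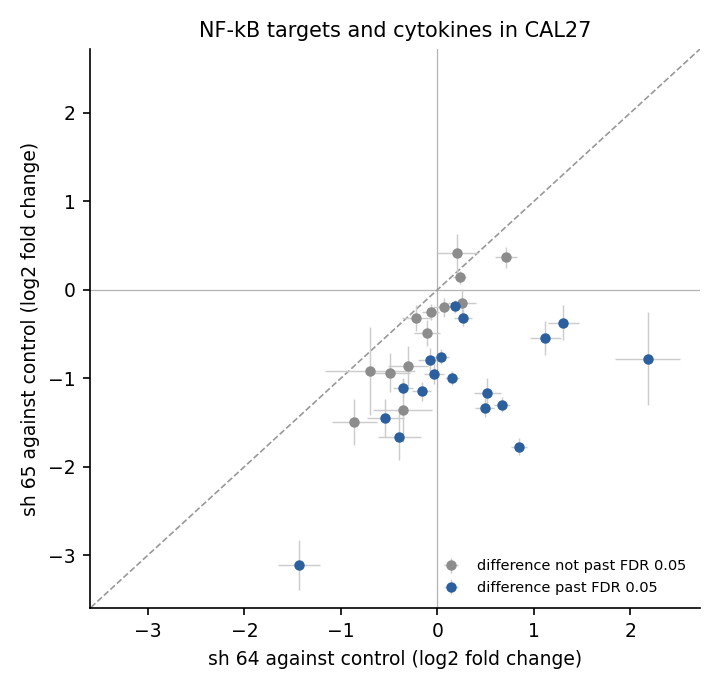
Log2 fold change against control of the 31 NF-kB targets and cytokines with sh 64 (horizontal axis) and sh 65 (vertical axis), with bars of 1 standard error and a dashed line of equal change; blue marks the 18 genes whose difference passed FDR 0.05. The median was 0.04 with sh 64 and -0.86 with sh 65.

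Overexpression effects differed between SCC25 and A253 in 871 of 15460 genes, 369 with a higher and 502 with a lower change in SCC25. The lines nevertheless shared calls: of 13340 genes tested in both, 351 rose in both and 94 fell in both, where independent lists would share 82.1 and 47, while 21 rose in A253 and fell in SCC25 and 41 did the reverse. Across genes the log2 changes correlated with Pearson r = 0.306 and Spearman rho = 0.172. The change of the chaperone CLU was higher in SCC25 by 2.08 and that of MMP13 by 1.91, and those of SPP1, DHRS9 and LAPTM5 were lower by log2 differences of -8.42, -5.43 and -3.87. The epidermal list differed by a median of 0.62 (camera adjusted p = 3.61e-07, and adjusted p = 0.119 with an estimated correlation), with 7 of 45 genes passing higher in SCC25 and 0 lower (10 and 0 adjusted over the list alone). The histone list differed by -0.53 (camera adjusted p = 1.15e-19, and adjusted p = 0.167 with an estimated correlation), with 20 of 47 genes lower and 0 higher (30 and 0 adjusted over the list alone). More changes were higher than lower in SCC25 without SCC25 control replicate 2 (180 and 138), SCC25 overexpression replicate 1 (185 and 141) or A253 control replicate 2 (354 and 337). The gene count was 527 by DESeq2, 127 with a 2-fold minimum, 976 with the replicate block, and 556, 318, 326 and 429 without SCC25 control replicates 1 and 2 and overexpression replicates 1 and 2.

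The overexpression effect common to both lines, an average over them in the additive model, passed in 1392 genes, 884 higher and 508 lower. A gene that moved mainly in 1 line can pass this test: by their separate tests 351 genes rose and 94 fell in both lines. Host defence genes rose in 17 of 29 cases and fell in 1 (20 and 2 adjusted over the list alone), with a median of 0.78 (camera adjusted p = 9.21e-08, and adjusted p = 0.0261 with an estimated correlation). Interferon genes rose in 21 of 43 cases and fell in 0 (26 and 1 adjusted over the list alone, median 0.24, camera adjusted p = 7.37e-14, and adjusted p = 0.0708 with an estimated correlation). Cholesterol synthesis genes fell in 10 of 25 cases and rose in 0 (13 and 0 adjusted over the list alone, median -0.16, camera adjusted p = 1.61e-05, and adjusted p = 0.424 with an estimated correlation). The gene count was 877 with the replicate block and 158 with a 2-fold minimum. Other splits of the libraries passed up to 16 lists by camera, against 11 for the real one. EHF itself had a common log2 change of 2.21 (SE 0.41, adjusted p = 0.0167), which did not pass with the block (adjusted p = 0.124) or without A253 control replicate 1 (adjusted p = 0.0564) or 3 (adjusted p = 0.0504). Its separate log2 changes were 3.02 in A253 and 0.99 in SCC25. The additive model counts that difference as spread, so its weak p does not put the rise within either line in doubt.

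Genes that followed EHF in each line were those that passed in all 3 comparisons, one way with overexpression and the other way with knockdown. Of 12658 genes tested in all 3, 55 rose with overexpression and fell with knockdown, and 27 did the reverse (82 in all, EHF included). Given the 331 and 89 genes that rose or fell in both overexpression comparisons, independent knockdown calls would give 30.4 and 8.8. ALOX5, the lipoxygenase of leukotriene synthesis, rose by 4.72 on the log2 scale in A253, went from 3 to 87 counts in SCC25 (ratio 34.6, counting interval 11.4 to 171) and changed by -2.15 in CAL27. LAPTM5 went from 2 to 245 counts in A253 (ratio 124, counting interval 33.9 to 1030), rose by 2.84 in SCC25 and changed by -2.03 in CAL27. The matrix metalloproteinase MMP7 changed by 2.34, 1.97 and -1.46, the lysosomal protease CTSS by 1.65, 1.38 and -1.23, and LCN2 by 4.08, 1.88 and -0.68. SDPR, a protein of caveolae, changed by 1.77, 0.98 and -0.73. The drug efflux transporter ABCG2 fell with overexpression (-0.73 and -0.90) and rose with knockdown (0.69; adjusted p = 0.0713 without CAL27 control replicate 2), as did the membrane protease TMPRSS13 (-0.91, -0.93 and 1.11) and the neurofilament NEFL (-0.72, -0.77 and 1.14). RNASE7 changed by 1.29, 1.02 and -1.92; its A253 call ended by DESeq2 (adjusted p = 0.114), on TPM without a filter (adjusted p = 0.0675), and without control replicate 1 (adjusted p = 0.128), control replicate 2 (adjusted p = 0.0572) or overexpression replicate 1 (adjusted p = 0.0781).

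Other genes moved the same way in overexpression and in knockdown: 83 rose and 15 fell in all 3 comparisons (98 in all), where independent knockdown calls would give 32.7 and 8.18. Of the 420 genes that overexpression moved alike in both lines, 42.9 percent passed with knockdown in either direction, against 19.1 percent of all genes. Of 41 interferon genes tested in all 3 comparisons, 13 rose in each and 0 were opposite; these include OAS1, IFIT2, IFIT3 and IFIH1, sensors and effectors of the antiviral response, chosen after their values were seen. The count of genes moved the same way was 58 by DESeq2, 37, 37 and 4 on TPM with a pseudocount of 1, of 0.1 and without a filter, 2 with a 2-fold minimum, and 59 when both knockdowns had to pass. It was 58 and 65 without CAL27 control replicates 1 and 2, and 65 without A253 control replicate 1. The count of opposite genes was 45 by DESeq2, 33, 34 and 8 on TPM with a pseudocount of 1, of 0.1 and without a filter, 5 with a 2-fold minimum, and 47 when both knockdowns had to pass. It was 52 and 47 without CAL27 control replicates 1 and 2, and 94 with the replicate block. Across genes, the log2 change of knockdown correlated with that of overexpression with Pearson r = -0.078 in A253 and 0.114 in SCC25 (Spearman rho -0.034 and 0.147).

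**Figure D4:**
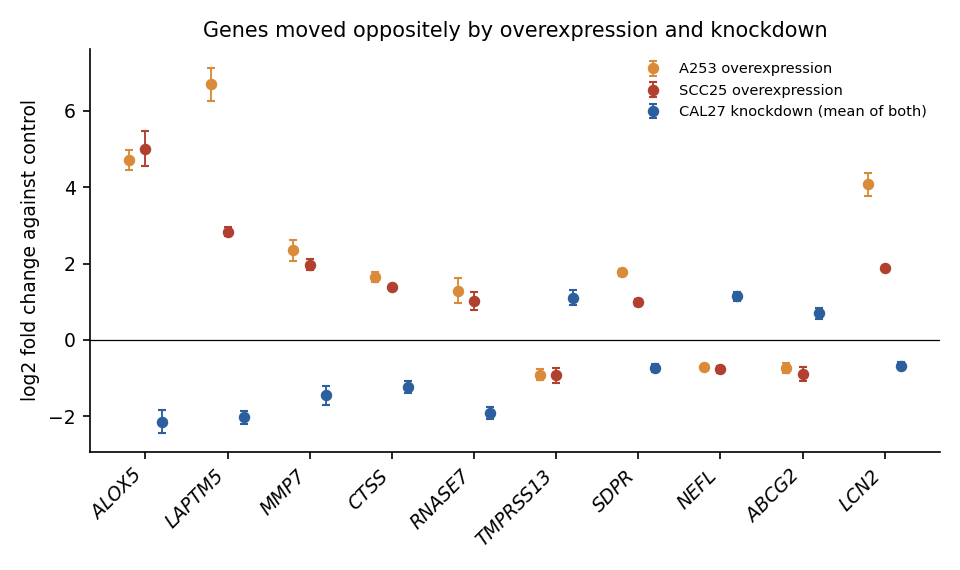
Log2 fold change against control (vertical axis) of the 10 genes, EHF left out, with the largest minimum change among those moved oppositely by overexpression and knockdown (horizontal axis). Values are for A253 and SCC25 overexpression and CAL27 knockdown (mean of both), with bars of 1 standard error. For ALOX5 the values were 4.72 in A253 and -2.15 in CAL27; the ALOX5 value in SCC25 and the LAPTM5 value in A253 rest on 3 and 2 control counts.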

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

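These results stood out because an effect differed between cell lines or between knockdowns by a test of the difference itself, an interaction term or a direct contrast. The test of the remaining EHF level in the knockdowns was chosen only after the result was seen.

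In the overexpression effect of SCC25 minus that of A253, 871 genes passed, and 556, 318, 326 and 429 without SCC25 control replicates 1 and 2 and overexpression replicates 1 and 2. Among genes with an average log2 CPM of at least 2, the largest differences on the high side were those of CLU (2.08), the gluconeogenic enzyme FBP1 (1.99) and MMP13 (1.91). On the low side they were SPP1 (-8.42), DHRS9 (-5.43) and LAPTM5 (-3.87), and EHF itself differed by -2.05. The SPP1 and LAPTM5 differences rest on 3 and 2 counts in the A253 controls. Lists with a higher change in SCC25 were epidermal differentiation (median difference 0.62), basal keratinocyte genes (0.10), epithelial adhesion (0.12), mesenchymal and matrix genes (0.22), type I interferon (0.16; adjusted p = 0.0944 without SCC25 overexpression replicate 1) and myoepithelial markers (0.35). Lists with a lower change were NRF2 targets (-0.22), glycolysis (-0.18), oxidative phosphorylation (-0.25), cholesterol synthesis (-0.21), S phase (-0.28), mitosis (-0.22) and replication-dependent histones (-0.53). These were the 13 lists past camera at the preset correlation, of 25 tested. With an estimated correlation 0 of the 25 passed, and 7 had an unadjusted p under 0.05. Fry called 14 of the 25.

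Between sh 65 and sh 64, 728 genes passed, and 263 and 419 without sh 64 replicates 1 and 2. Among genes with an average log2 CPM of at least 2, the largest differences on the high side were those of KRT4 (3.34), LYPD1 (1.97) and ALPP (1.85). On the low side they were SERPINB2 (-2.74), IL1A (-2.62) and CYP1A1 (-2.53). Lists lower with sh 65 were NF-kB targets (median difference -0.76), host defence (-0.515), cholesterol synthesis (-0.51), ERK feedback (-0.47), ERBB receptors and ligands (-0.35), immediate early genes (-0.30), hypoxia (-0.27), endoplasmic reticulum chaperones (-0.17), basal keratinocyte genes (-0.11), glycolysis (-0.074) and NRF2 targets (-0.062). Lists higher with sh 65 were histones (0.30), mitosis (0.14), interferon (0.11), the ATF4 response (0.094), epithelial adhesion (0.081) and S phase (0.06). These were the 17 lists past camera at the preset correlation, of 25 tested. With an estimated correlation 0 of the 25 passed, and 7 had an unadjusted p under 0.05. Fry called 12 of the 25. Without sh 64 replicate 1 the adhesion and ATF4 lists did not pass (adjusted p = 0.0535 and 0.0849), and without sh 65 replicate 1 the NRF2, glycolysis and ATF4 lists did not (adjusted p = 0.0552, 0.0662 and 0.0662).

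The lower level of NF-kB targets with sh 65 was weighed against the remaining EHF level, a single library and unequal library totals. EHF fell with sh 64 by 0.852 of its log2 change with sh 65, so an effect in proportion to EHF would give a list median of -0.73 with sh 64. The observed median was 0.037, with 16 members higher and 15 lower, against 3 and 28 with sh 65. Its interval of -0.162 to 0.231 came from resampling the list members, which does not measure the spread between libraries. The list was taken up because it differed between the knockdowns in these same libraries, so this is no independent test. Within these limits the median of this list with sh 64 did not follow a proportional effect. The median difference nearest 0 was -0.734 when each knockdown library was left out in turn and -0.751 when libraries were thinned to equal totals, the only measure of depth matched, which argues against a single library or unequal totals. An effect of 1 hairpin on other transcripts, a threshold in the response to EHF or a difference between the cell populations could each be consistent with these values, and none of them was tested.

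The lower level of histone, S phase and mitosis genes in SCC25 overexpression was weighed against gene length. Unequal library totals were weighed for S phase and mitosis only, and carry-over of RNA without a poly(A) tail for histones only. After the trend with gene length was removed the list median nearest 0 of S phase and mitosis was -0.222 and the histone median was -0.453, which argues against length. After thinning to equal library totals the median of S phase and mitosis nearest 0 was -0.182, which argues against unequal totals for these lists. Histone genes were not tested after thinning. Histone mRNAs lack a poly(A) tail, but 170 other RNAs without one had a median log2 change of 0.156 (14 higher and 2 lower past the threshold), which argues against lower carry-over as the whole cause. The histone fall may reflect, together with the S phase and mitosis lists, a smaller share of dividing cells, a hypothesis drawn from these same data that was not itself tested. These lists did not move together with CAL27 knockdown. There, at an unadjusted p under 0.05 by edgeR, 27 S phase genes fell and 0 rose, and 10 mitosis genes fell and 1 rose. By the same measure 14 histone genes rose and 0 fell. Doxycycline stays open, as no SCC25 library separates it from EHF. In A253, where overexpression came with the same drug, the histone, S phase and mitosis medians were 0.057, -0.015 and -0.014.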

How the results depend on the processing

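No gene named by the rule and no list past camera reversed its direction in A253, SCC25, the mean knockdown, between the knockdowns or between the lines. With each knockdown alone and for the effect common to both lines, EHF alone among genes and lists was followed in this way. The balance of genes called higher and lower did turn in some settings: in SCC25 (1728 and 1642) with no filter on low counts (1713 and 1949), on TPM with a pseudocount of 1 (575 and 659) or 0.1 (731 and 873) and without control replicate 1 (1800 and 1839), in the mean knockdown (1346 and 1214) on TPM (658 and 970, 659 and 976, and 389 and 466 without a filter), with sh 65 (1038 and 956) by DESeq2 (582 and 588), and between the lines (369 and 502) without SCC25 control replicate 2 (180 and 138), SCC25 overexpression replicate 1 (185 and 141) or A253 control replicate 2 (354 and 337). Of the values that answer a comparison, 125 kept their side of the threshold or stayed within 1.5 times, 40 counts moved and 2 calls were lost under the settings other than leaving out a library, and of those for a single gene or list 1806 were kept, 172 lost their call, 38 counts moved and 1 gained a call. RLE size factors, no filter on low counts and a CPM minimum left each of these counts within 1.5 times. The counts of called genes depended on the tool, on the minimum change and on single libraries. DESeq2 called 1540 in SCC25, 1461 in the mean knockdown, 1191 with sh 64, 1170 with sh 65, 441 between the knockdowns, 527 between the lines, 562 shared by the knockdowns and 45 opposite genes. Limma on TPM with a pseudocount of 1, with 0.1, and with 1 and no filter called 699, 687 and 561 genes in A253, 1234, 1604 and 96 in SCC25, 1628, 1635 and 855 in the mean knockdown and 33, 34 and 8 opposite genes. Without a filter EHF in SCC25, on the score rather than TPM, changed by 0.963 (adjusted p = 0.0631). A 2-fold minimum left 157 genes in A253, 192 in SCC25, 293 in the mean knockdown, 308 with sh 64 and 341 with sh 65. It left 120 between the knockdowns, 127 between the lines and 158 for the effect common to both lines. It also left 146 shared by the knockdowns and 5 opposite genes, since fewer genes meet both conditions. Requiring both knockdowns to pass left 47 opposite genes. With the replicate block 1260 genes differed between the knockdowns and 877 passed for the effect common to both lines, where EHF changed by 2.207 (adjusted p = 0.124).

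Gene lists past the camera threshold were 9 in A253 by DESeq2 and 9 on TPM without a filter. With an estimated correlation 0 lists passed in A253, SCC25 or the mean knockdown, with 4, 5 and 7 at an unadjusted p under 0.05, while the preset correlation called 5, 16 and 11 and fry called 8, 10 and 9. With sh 64, with sh 65, between the knockdowns and between the lines 0 passed as well (7 in each at an unadjusted p under 0.05), against 16, 13, 17 and 13 by the preset correlation and 12, 10, 12 and 14 by fry. For the effect common to both lines 1 passed (3 at an unadjusted p under 0.05), against 11 and 5. As 2 or 3 libraries per group leave the estimated version few degrees of freedom, its lack of passes cannot decide whether lists changed. Apart from the 2-fold minimum, the joint condition and the estimated correlation, the cause was not tested.

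Leaving out each library in turn gave 658 to 1036 genes in A253, 2124 to 3639 in SCC25, 937 to 3038 in the mean knockdown, 866 to 2876 with sh 64, 879 to 2026 with sh 65, 263 to 1048 between the knockdowns, 318 to 936 between the lines, 390 to 1218 shared by the knockdowns and 47 to 91 opposite genes. EHF common to both lines ranged from 2.042 (adjusted p = 0.0504 without A253 control replicate 3, and 0.0564 without control replicate 1) to 2.472. The lowest counts came without control replicate 1 in A253, the mean knockdown, sh 64, sh 65 and the shared genes, without overexpression replicate 2 in SCC25, without sh 64 replicate 1 between the knockdowns, without SCC25 control replicate 2 between the lines and without CAL27 control replicate 2 for opposite genes. Counts also moved by more than 1.5 times without SCC25 overexpression replicate 1 (2228 genes, and 326 between the lines), without CAL27 control replicate 2 (1037 in the mean knockdown, 940 with sh 64, 937 with sh 65 and 446 shared), without CAL27 control replicate 1 (52 opposite genes), without sh 64 replicate 1 (899 with sh 64 and 530 shared) or 2 (419 between the knockdowns), and, between the lines, without SCC25 overexpression replicate 2 (429) or control replicate 1 (556). Among single genes and lists 1395 values were kept, 91 lost their call, 36 counts moved and 2 gained a call. A group left with 1 library was assumed to vary like the others. In simulated data at these depths edgeR recovered 61.2 percent of 1.5-fold changes in A253, 76.1 percent in SCC25 and 80.6 percent in the mean knockdown. Between the lines it recovered 28.4 percent and between the knockdowns 59.7 percent, with 10.8 and 12 percent of its calls false. Genes that moved the same way numbered 58 by DESeq2, 37, 37 and 4 on TPM, 2 with a 2-fold minimum, 59 when both knockdowns had to pass and 58 to 120 without 1 library.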

Other observations

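The tests of expression level, library totals and doxycycline on genes moved the same way were chosen only after the result was seen.

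Several gene lists did not pass in the main comparisons. In A253 (camera adjusted p = 0.106 to 0.856) these were basal keratinocyte genes (median -0.05), adhesion (0.02), mesenchymal and matrix genes (0.04), NRF2 targets (-0.02), other redox enzymes (0.03), glycolysis (-0.02), hypoxia (0.02), the ATF4 response (0.00), chaperones (0.06), cholesterol synthesis (-0.07), S phase (-0.02), mitosis (-0.01), ERBB (-0.02), ERK feedback (0.03), immediate early genes (0.04), other ETS factors (-0.02), histones (0.06), and fibroblast (-0.10), endothelial (0.09) and myoepithelial (-0.16) markers. In SCC25 (camera adjusted p = 0.0883 to 0.913) they were other redox enzymes (-0.03), hypoxia (0.01), the ATF4 response (-0.03), NF-kB targets (0.10, with 8 of 30 higher and 2 lower), ERBB (-0.15), ERK feedback (-0.15), other ETS factors (0.07) and fibroblast markers (0.02). The fibroblast collagens COL1A2 and COL1A1, chosen after their values were seen, were higher by 1.44 and 0.84 in SCC25. In the CAL27 knockdown (camera adjusted p = 0.111 to 0.95) they were basal keratinocyte genes (-0.02, though the mean was 0.23), other redox enzymes (0.10, past the threshold by DESeq2, without sh 65 replicate 1 and without control replicate 2, adjusted p = 0.0289, 0.0373 and 0.0418), glycolysis (-0.04), hypoxia (0.13), chaperones (-0.05), cholesterol synthesis (0.02), mitosis (-0.05), ERBB (0.07), ERK feedback (-0.04), immediate early genes (0.08), other ETS factors (-0.13), and fibroblast (0.29), salivary (0.20) and myoepithelial (0.26) markers. Leukocyte markers had fewer than 5 tested members in each line, and mitochondrial transcripts were absent from the tables.

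The genes opposite in overexpression and knockdown were few in most lists: host defence had RNASE7, LCN2 and SAA1, the mesenchymal list PMEPA1, CDH11 and FSTL1, and the basal, NRF2 and hypoxia lists SOX2, AKR1C2 and ERO1L, 1 each. Genes that moved the same way included CLU (0.73 in A253, 2.83 in SCC25 and 0.64 in CAL27), CYP1A1 (0.77, 1.62 and 1.80) and MMP13 (2.03, 3.96 and 2.01); these members were chosen after their values were seen. The MMP13 call in CAL27 ended without either control (adjusted p = 0.108 and 0.0934).

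The 98 genes that moved the same way exceed the 40.9 expected of independent knockdown calls, given the 420 genes that overexpression moved alike in both lines. The 82 opposite genes exceed their expectation as well, so this excess is not one of direction alone. Shuffling the knockdown calls within deciles of expression, with the overexpression calls kept, gave at most 62 genes moved the same way (mean 44.4) and at most 69 opposite genes (mean 44.2). This argues against expression level alone deciding which genes can be called. Thinning the CAL27 libraries to equal totals left at least 92 genes, where shuffles of the thinned calls gave at most 59, which argues against unequal totals. Within the overexpression comparisons doxycycline cannot be told apart from EHF, since 0 pairs of groups differ in the drug and not in EHF. The labels name doxycycline for no CAL27 library, so the drug as labelled does not account for the changes with knockdown. No biological explanation was tested.

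The real grouping was compared with other splits of the libraries. In A253 the 10 splits are too few for a share under 0.05. The real split called 1156 genes against a highest other count of 0, and 1 of the 10 splits, the real one, reached that count. It called 5 lists against a highest other count of 7. As 6 of the 10 splits reached 5 lists, that number does not stand out from other splits. For the effect common to both lines, 1 of 60 splits, the real one, reached 1392 genes and the highest other count was 302. This is the smallest share that 60 splits allow, so it argues against chance for that count without excluding it. For its 11 lists, 17 of 60 splits reached as many (highest other count 16), so chance is not excluded there.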
